A study of Mus musculus with 12 samples.

How the data were processed

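RNA was measured in primary neural precursor cells of adult female C57BL/6 mice that were kept undifferentiated in culture. Cells received 100 µM hydrogen peroxide for 1 h or 8 h, or a sham exposure to phosphate-buffered saline, and each of these 3 groups holds 4 biological replicates, 12 samples in all. Per the labels, control, 1 h and 8 h samples came from each of 4 animals, total RNA was column-purified, poly-A libraries were made with a stranded kit, and a minimum depth was set for all samples. The time at which control cells were collected and the strand setting used for counting are not given in the sources used here.

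The deposited files hold the authors' tests and no values of single samples: the number of columns with per-sample values was 0. Per the file headers, the authors counted reads per gene with featureCounts, on genome build GRCm38 per the labels, and tested genes with the edgeR GLM pipeline with tagwise dispersion and a likelihood ratio test. A second deposited table, per the file headers, comes from voom with sample quality weights and limma. Fold changes and mean expression are deposited in log2 units, the latter as log2 CPM, a count scaled to library size, averaged over all samples. The likelihood ratio of the GLM table and the moderated t, B and F values of the voom table are each deposited as a test statistic, a score. The deposited p-value columns hold the p-value of the authors' tests and its Benjamini-Hochberg adjusted form. The deposited tables also hold other columns that are not measurements of expression, such as the summed exon length of each gene, the authors' calls, and numbers of genes per set. The deposited tables are named as filtered for genes and with outlier samples removed. Which samples were removed is not given in the sources used here, so the number of samples per group behind each test is unknown and at most 4, and the aligner, the annotation release, the design formula, the tool versions and the depth of each sample are unknown as well. The authors also deposited gene set tests, as p-value columns of camera for the hallmark, KEGG, WikiPathways and Reactome collections and of overlap tests for hallmark and Gene Ontology sets. Their other collections and rankings were not used here.

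The design fixed before the data were examined called for a quasi-likelihood test of counts with the animal as a block, and named the authors' deposited GLM table as the test to use if no per-sample values were present. That table was therefore used as deposited, and genes were called changed at an adjusted p below 0.05. The deposited adjusted p matched a Benjamini-Hochberg correction over the 15478 genes of each comparison to within 1.3e-15, and the authors' calls differed from this threshold for 0 genes. The log2 fold change of 8 h against 1 h equalled the difference of the other comparisons to within 1e-14. The standard error given after a log2 fold change was computed here, as the absolute log2 fold change divided by the square root of the authors' likelihood ratio, and is called the implied standard error. Its median ratio to the standard error of the authors' voom fit was 1.06 at 1 h, 1.01 at 8 h and 1.00 for 8 h against 1 h. At 8 h, and for 8 h against 1 h, the deposited p of 11 genes is 0, and no p is printed for these.

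Before the data were examined, 29 gene lists of 638 entries were written for stress responses, cell cycle, repair, metabolism and the cell types that such cultures may hold. Among the table's genes, 566 entries were found by symbol, 12 by Ensembl identifier and 3 by synonym, and 57 were not found. Each list was tested with cameraPR of limma 3.58.1 in R 4.3.3, a two-sided competitive test, on the square root of the likelihood ratio with the sign of the fold change and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg correction over the 29 lists of a comparison. No correlation could be estimated without per-sample values, so a correlation of 0.05 stands in for an estimated one. Some genes belong to more than 1 list. List counts were also adjusted over the list alone. The named genes were chosen by a rule written before the data were examined. Per comparison it takes up to 8 genes with the highest and up to 8 with the lowest log2 fold change among changed genes with a mean log2 CPM of at least 1 and a symbol that is not a placeholder. It also takes up to 4 members of each list described, those with the smallest adjusted p, their values at the other time, and Hmox1, Cdkn1a, Fos, Cat, Sox2 and Mki67. Some genes, sets and families that the rules choose are not reported here. Any other gene named was chosen after its values were seen, and is said to be so.

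The threshold and the list tests were tried on simulated data. Values were drawn for each gene independently with the implied standard errors and tested with those same errors. The share of false calls is thereby set near the threshold. The simulation shows what could be recovered if those errors hold, and cannot check the authors' calls or lists of correlated genes. Of 100 genes simulated with a 1.5-fold change, 76 were recovered at 1 h, 81 at 8 h and 80 for 8 h against 1 h. Of 100 genes simulated with a 2-fold change, 90, 89 and 86 were recovered, and 5.00%, 4.57% and 5.21% of all calls were genes simulated without change. Both lists shifted by 0.3 (log2) were found in each comparison, together with 2 of the other 27 lists at 1 h and 0 at the later comparisons. Calls at 1 h and 8 h share the control samples, so their overlap was also compared with 100 simulations of unchanged groups with shared controls. Coordinates are from GENCODE mouse release 21, matched by Ensembl identifier for 15469 genes. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

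Alternatives chosen before the data were examined were the authors' voom table, median centring of the fold changes, only genes with a mean log2 CPM of at least 1, an adjusted p below 0.01, an added minimum of 1 for the absolute log2 fold change, and correction over the 3 comparisons together. For lists they were the voom statistic, the correlation of 0.05, the same filter on expression and a rank-based cameraPR. Alternatives that need counts or values of single samples could not be computed from the deposited files.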

Results

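The series measured poly-A RNA by sequencing in undifferentiated neural precursor cells of adult mice, cells that divide in culture and can form neurons, astrocytes and oligodendrocytes. Its stated subject is the effect of reactive oxygen species on such cells. The 4 control samples received phosphate-buffered saline, 4 samples received 100 µM hydrogen peroxide for 1 h and 4 received it for 8 h. The depth of each sample is unknown because the authors' deposited table holds 1 fold change per gene and comparison and no counts. That table covers 15478 genes, with mean expression from -1.98 to 12.96 log2 CPM, and 12408 of them reach at least 1. All log2 fold changes of genes below come from it, each followed where it matters by the implied standard error after the sign ±. The number of samples per group behind each test is at most 4 and is not stated, so no count of samples that share a direction can be given.

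The comparison of 1 h with control addresses the early response to peroxide. Because the collection time of the control cells is not given, time in culture cannot be told apart from peroxide here. The same holds for 8 h against control. After 1 h, immediate-early genes, p53 targets, genes of the integrated stress response and NRF2 targets were higher than in control cells, and genes of cholesterol synthesis were lower. The authors' deposited table calls 3166 genes that rose and 3440 that fell, 42.7% of those tested, with a median absolute log2 fold change of 0.28 among them. Of the genes that changed at least 2-fold, 618 rose and 28 fell. Heme oxygenase Hmox1, which breaks down heme, rose 2.43-fold in the authors' deposited table, by 1.28 ± 0.07 on the log2 scale (adjusted p 4.4e-71).

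Of the named genes, the highest rise at 1 h in the authors' deposited table was that of the linker histone gene H1f3, 3.19 ± 0.18 (adjusted p 8.4e-65). The AP-1 subunit gene Fosb rose by 3.09 ± 0.15 and Osgin1, an oxidative stress gene, by 2.78 ± 0.11 in the authors' deposited table. The others in this group of 8 were, with log2 fold changes from the authors' deposited table, the claudin gene Cldn15 (2.96 ± 0.20), the ubiquitin ligase gene Trim17 (2.90 ± 0.19), Ccno (2.64 ± 0.15), the relaxin gene Rln1 (2.55 ± 0.29) and the exonuclease gene Isg20 (2.51 ± 0.15). Several of these lie downstream of an expressed gene on the same strand: Cldn15 starts 0.382 kb past the end of Fis1, Isg20 2.21 kb past Aen, Rln1 13.9 kb past Plgrkt, Ccno 18.4 kb past Dhx29, Osgin1 23.0 kb past Mlycd and Fosb 46.0 kb past Cd3eap. Such a neighbour within 50 kb was also found for 26.5% of 3540 genes with a mean below 2 log2 CPM that were not called as rising at least 2-fold. Among 560 such genes that were, it was found for 62.5%. Of the genes just listed only Cldn15 and Rln1 lie below that level, so these shares are no baseline for the others. Sox7, which fell, also starts 23.8 kb past Pinx1. Whether a neighbour has a part in the change of any single gene was not tested. Falls were smaller. Rab26, a small GTPase gene, fell in the authors' deposited table by 1.46 ± 0.16 (adjusted p 1.9e-17) and the thyrotropin receptor gene Tshr by 1.10 ± 0.25 (adjusted p 6.6e-05). The authors' deposited table also gives falls for the noncoding 7SK RNA gene Rn7sk (-1.08 ± 0.19), Gucy1a2 (-1.03 ± 0.21), the serotonin receptor gene Htr1b (-0.95 ± 0.08), the long noncoding RNA gene Lncpint (-0.89 ± 0.09), Sox7 (-0.89 ± 0.07) and Shroom4 (-0.87 ± 0.07). Because the libraries were poly-A, the values of H1f3 and Rn7sk need not hold for their RNA without a poly-A tail. On GRCm38, H1f3 lies on chromosome 13 from 23553262 to 23560686, Fosb on chromosome 7 from 19302696 to 19310051, Hmox1 on chromosome 8 from 75093621 to 75100589 and Rab26 on chromosome 17 from 24527241 to 24534210.

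Of 36 immediate-early genes, 29 rose and 3 fell at 1 h, with a median log2 fold change of 0.79 (adjusted p of the list 3.2e-36). In the authors' deposited table the transcription factor gene Klf4 rose 2.82-fold, Fosl2 rose by 1.10 ± 0.05 and Fosl1 by 0.94 ± 0.04, and Fos rose by 1.51 ± 0.13 (adjusted p 1.1e-29). Of 44 p53 targets, 31 rose and 4 fell, with a median of 0.30 (adjusted p 4.8e-51). The authors' deposited table gives 2.14 ± 0.06 for Pmaip1, whose product Noxa promotes apoptosis, 1.20 ± 0.04 for Trp53inp1, 1.16 ± 0.03 for Sesn2 and 1.06 ± 0.04 for Mdm2, the ubiquitin ligase of p53. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose in the authors' deposited table by 0.72 ± 0.03 (adjusted p 8.8e-110). Of 25 apoptosis regulators, 12 rose and 5 fell (median 0.14, adjusted p 1.2e-06). Among them, the authors' deposited table gives 1.60 ± 0.06 for Bbc3 (Puma), 0.89 ± 0.06 for Bcl2l11 (Bim) and 0.42 ± 0.05 for the death receptor gene Tnfrsf10b.

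Of 25 NRF2 targets, 19 rose and 2 fell (median 0.23, adjusted p 1.3e-13). Beside Hmox1 and Osgin1, the authors' deposited table gives 1.02 ± 0.06 for Srxn1, which repairs oxidized peroxiredoxins, and 0.84 ± 0.07 for the cystine transporter gene Slc7a11. Of 27 integrated stress response genes, 17 rose and 3 fell (median 0.21, adjusted p 4.4e-14). The authors' deposited table gives 1.11 ± 0.05 for Ppp1r15a, a regulator of the eIF2 alpha phosphatase, 0.64 ± 0.04 for Atf4 and 0.61 ± 0.03 for the amino acid transporter gene Slc3a2. Of 7 metal-responsive genes, 4 rose and 1 fell (median 0.52, adjusted p 4.4e-07), and in the authors' deposited table the zinc exporter gene Slc30a1 rose by 0.90 ± 0.05, Mt2 by 0.80 ± 0.06 and Mt1 by 0.52 ± 0.05. Of 18 circadian clock genes, 9 rose and 3 fell (median 0.12, adjusted p 3.2e-05), though the adjusted p was 0.095 with a rank-based test. The authors' deposited table gives 0.91 ± 0.07 for Nfil3, 0.89 ± 0.06 for Bhlhe40, 0.88 ± 0.05 for Per1 and 0.87 ± 0.05 for Nr1d1. Of 25 cholesterol biosynthesis genes, 0 rose and 21 fell (median -0.27, adjusted p 6.5e-07), and the authors' deposited table gives -0.35 for Hmgcs1, -0.41 for Lss, -0.34 for Sqle and -0.35 for Nsdhl, each ± 0.05.

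Of 31 genes of the G1/S transition and DNA replication, 25 rose and 1 fell at 1 h (median 0.27, adjusted p 4.1e-08). The authors' deposited table gives 0.64 ± 0.06 for the replication licensing gene Cdt1, 0.38 ± 0.04 for the ribonucleotide reductase gene Rrm2, 0.31 ± 0.04 for Pcna and 0.30 ± 0.04 for Mcm7. Of 30 G2/M genes, 14 rose and 0 fell (median 0.16, adjusted p 0.0085), but the adjusted p was 0.079 with a correlation of 0.05. Aurkb rose in the authors' deposited table by 0.41 ± 0.08, Birc5 by 0.34 ± 0.07, Cdca8 by 0.33 ± 0.08 and Cdk1 by 0.30 ± 0.07, whereas the proliferation marker Mki67 had 0.05 ± 0.06 (adjusted p 0.51). Of 21 peroxide and superoxide scavengers, 9 rose and 0 fell (median 0.11, adjusted p 0.048, and adjusted p 0.16 with a correlation of 0.05). The authors' deposited table gives 0.26 ± 0.03 for Prdx6, 0.17 ± 0.04 for Sod1, 0.15 ± 0.04 for Gpx4 and 0.17 ± 0.05 for Gpx1, and -0.03 ± 0.04 (adjusted p 0.54) for catalase, Cat. Of 17 hypoxia-responsive genes, 7 rose and 0 fell (median 0.09, adjusted p 0.0085, and adjusted p 0.053 with a correlation of 0.05). The authors' deposited table gives 0.54 ± 0.04 for Ddit4, 0.42 ± 0.04 for Kdm3a, 1.94 ± 0.25 for Ankrd37, which starts 27.6 kb past the end of Snx25, and 0.36 ± 0.07 for Pdk1. Of 14 interferon response genes, 5 rose and 0 fell (median 0.18, adjusted p 0.038, but adjusted p 0.10 with a correlation of 0.05, 0.083 with the filter on expression and 0.061 with ranks). The authors' deposited table gives 1.00 ± 0.07 for the peptide transporter gene Tap1, 0.47 ± 0.11 for Irf1, 1.38 ± 0.30 for Psmb9 and 1.78 ± 0.39 for Psmb8, which starts 0.496 kb past the end of Tap1.

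The progenitor, oligodendrocyte and astrocyte lists were lower at 1 h by small amounts. No list was adjusted for gene span at 1 h, when long genes in general were lower. The longest eighth of the protein-coding genes examined for span had a median log2 fold change of -0.29, and the shortest 0.08. A trend with span therefore cannot be told apart from a change particular to these lists. Of 24 neural stem and progenitor cell genes, 2 rose and 8 fell (median -0.09, adjusted p 0.0085, but adjusted p 0.069 with a correlation of 0.05 and 0.054 with ranks). The growth factor receptor gene Egfr fell in the authors' deposited table by 0.54 ± 0.04, Tnc by 0.61 ± 0.05, Slc1a3 by 0.33 ± 0.04 and Notch1 by 0.33 ± 0.04, and the stem cell factor gene Sox2 fell by 0.23 ± 0.03 (adjusted p 4.9e-11). Of 18 oligodendrocyte lineage genes, 0 rose and 7 fell (median -0.21, adjusted p 0.0085, and adjusted p 0.055 with a correlation of 0.05). The authors' deposited table gives -0.64 ± 0.04 for Olig2, -0.42 ± 0.05 for Pdgfra, -0.32 ± 0.06 for Sox10 and -0.24 ± 0.04 for Olig1. Of 15 astrocyte genes, 2 rose and 9 fell (median -0.29, adjusted p 0.026, but adjusted p 0.085 with a correlation of 0.05 and 0.074 with the filter on expression). The authors' deposited table gives -0.52 ± 0.07 for Slc4a4, -0.34 ± 0.05 for the glutamate transporter gene Slc1a2 and -0.29 ± 0.03 for Aldh1l1, and a rise of 0.26 ± 0.04 for the connexin gene Gja1.

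The other 13 lists did not pass at 1 h. Of 25 homologous recombination genes, 7 rose and 2 fell (adjusted p 0.19), of 22 neuronal lineage genes 1 rose and 5 fell (adjusted p 0.35), of 19 endoplasmic reticulum chaperones 3 rose and 10 fell (adjusted p 0.55), and of 19 Notch pathway genes 5 rose and 7 fell (adjusted p 0.12). Of 14 NF-kB targets, 5 rose and 1 fell (adjusted p 0.26), of 20 glycolysis genes 5 rose and 2 fell (adjusted p 0.26), and of 22 heat shock genes 5 rose and 5 fell (adjusted p 0.55). Of 20 genes of base excision and strand break repair, 3 rose and 3 fell (adjusted p 0.93), and of 14 mitochondrial biogenesis genes 2 rose and 4 fell (adjusted p 0.69). Of the 10 mitochondrially encoded genes in the table, 0 rose and 1 fell (adjusted p 0.89). Markers of other cell types were tested as well. Of the 4 microglia genes present, 2 rose and 0 fell (adjusted p 0.26), of 8 endothelial and mural cell genes 3 rose and 1 fell (adjusted p 0.69), and of 7 ependymal genes 2 rose and 0 fell (adjusted p 0.30). The ependymal gene Foxj1, with a mean of 5.00 log2 CPM, rose in the authors' deposited table by 0.32 ± 0.07 (adjusted p 8.7e-06). Others that rose in the authors' deposited table include Csf1r (1.34 ± 0.37), Esam (1.77 ± 0.34), Pecam1 (1.18 ± 0.43) and Ak7 (1.46 ± 0.35), these 4 with a mean below 0 log2 CPM. Ak7 starts 2.95 kb past the end of Gskip, Esam 3.45 kb past Msantd2 and Pecam1 29.7 kb past Ddx5.

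The comparison of 8 h with control addresses the later response. After 8 h, genes of the cell cycle, of DNA replication and of homologous recombination were far lower than in control cells, and so were markers of the oligodendrocyte and neuronal lineages. Targets of p53 and NRF2 were higher, most of them further above control than at 1 h. The authors' deposited table calls 4243 genes that rose and 4371 that fell, 55.7% of those tested, with a median absolute log2 fold change of 0.35 among them. Of the genes that changed at least 2-fold, 408 rose and 899 fell. Hmox1 rose 4.31-fold, by 2.11 ± 0.07 on the log2 scale (adjusted p 1.3e-187), and Mki67 fell by 2.81 ± 0.06, both in the authors' deposited table.

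Of the named genes, the deepest fall at 8 h in the authors' deposited table was that of the DNA helicase gene Pif1, -4.49 ± 0.19 (adjusted p 8.5e-123). The authors' deposited table also gives -3.45 ± 0.16 for the vesicle protein gene Rph3a, -3.36 ± 0.28 for Arhgef39, -3.20 ± 0.16 for the mitotic phosphatase gene Cdc25c, -3.07 ± 0.18 for Ankle1, -3.07 ± 0.11 for Sapcd2, -3.00 ± 0.14 for the kinesin gene Kif14 and -2.95 ± 0.11 for the kinesin gene Kif2c. Among genes that the naming rule admits, with a mean log2 CPM of at least 1, the highest rise in the authors' deposited table was that of Rln1, 3.50 ± 0.23, an 11.3-fold rise (adjusted p 8.0e-49). The authors' deposited table gives 3.27 ± 0.21 for the transcription factor gene Grhl3, 3.06 ± 0.18 for Tcea3, 2.88 ± 0.12 for the kinase gene Ptk2b, 2.88 ± 0.20 for Ptprv, 2.85 ± 0.16 for the adhesion molecule gene Icam1, 2.82 ± 0.20 for Gask1b and 2.66 ± 0.11 for the actin-bundling gene Espn. On GRCm38, Pif1 lies on chromosome 9 from 65587160 to 65595967, Rln1 on chromosome 19 from 29331170 to 29334670, and Mki67 on chromosome 7 from 135689784 to 135716361.

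All 30 G2/M genes fell at 8 h (median -2.37, adjusted p 1.2e-96), as did all 31 genes of the G1/S transition and DNA replication (median -1.30, adjusted p 3.2e-45). The topoisomerase gene Top2a fell in the authors' deposited table by 2.41 ± 0.05, the mitotic kinesin gene Kif11 by 2.67 ± 0.07 and the kinetochore gene Cenpf by 2.84 ± 0.08. For replication, the authors' deposited table gives -1.74 ± 0.05 for the helicase subunit gene Mcm5, -1.43 ± 0.05 for Mcm3, -1.30 ± 0.04 for Rrm2 and -1.48 ± 0.05 for the DNA ligase gene Lig1. Of 25 homologous recombination genes, 2 rose and 20 fell (median -0.85, adjusted p 3.2e-09). The authors' deposited table gives -1.78 ± 0.09 for Brca1, -1.96 ± 0.10 for the exonuclease gene Exo1, -2.21 ± 0.11 for Fancd2 and -2.08 ± 0.11 for Fanca.

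Of 44 p53 targets, 41 rose and 1 fell at 8 h (median 0.80, adjusted p 1.6e-60). Pmaip1 rose in the authors' deposited table by 1.95 ± 0.06, Dcxr by 1.89 ± 0.05, Cdkn1a by 1.25 ± 0.03 and Ccng1 by 1.15 ± 0.03. Of 25 apoptosis regulators, 15 rose and 3 fell (median 0.30, adjusted p 1.3e-07), with 1.52 ± 0.08 for the death receptor gene Fas, 1.43 ± 0.04 for Tnfrsf10b and 0.97 ± 0.05 for Apaf1 in the authors' deposited table. Of 25 NRF2 targets, 24 rose and 1 fell (median 0.63, adjusted p 1.8e-24). The authors' deposited table gives 1.17 ± 0.05 for the glutathione synthesis gene Gclm, 0.85 ± 0.04 for the thioredoxin reductase gene Txnrd1 and 0.82 ± 0.04 for the autophagy receptor gene Sqstm1. Of 27 integrated stress response genes, 21 rose and 4 fell (median 0.43, adjusted p 3.1e-09), with 1.48 ± 0.07 for Slc7a11, 1.05 ± 0.05 for Eif4ebp1, 0.96 ± 0.03 for Sesn2 and 0.72 ± 0.03 for Slc3a2 in the authors' deposited table. Of 7 metal-responsive genes, 4 rose and 0 fell (median 0.21, adjusted p 2.8e-05), with 0.99 ± 0.05 for Mt1, 0.97 ± 0.06 for Mt2 and 0.21 ± 0.04 for Mt3 in the authors' deposited table. Of 21 scavenger genes, 10 rose and 3 fell (median 0.15, adjusted p 0.023, and adjusted p 0.097 with a correlation of 0.05). The authors' deposited table gives 0.83 ± 0.03 for Prdx6, 0.57 ± 0.04 for Cat (adjusted p 7.0e-54), 0.36 ± 0.04 for Gpx8 and 0.21 ± 0.04 for Sod1. Of 18 circadian clock genes, 9 rose and 5 fell (median 0.22, adjusted p 0.031, but adjusted p 0.11 with a correlation of 0.05, 0.052 with the filter on expression and 0.076 with ranks). The authors' deposited table gives 0.76 ± 0.08 for Bhlhe41, 0.64 ± 0.04 for Nr1d2, 0.54 ± 0.04 for Tef and 0.54 ± 0.05 for Per3.

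Of 18 oligodendrocyte lineage genes, 0 rose and 17 fell at 8 h (median -0.93, adjusted p 2.7e-14). Pdgfra, the receptor of oligodendrocyte precursor cells, fell in the authors' deposited table by 2.89 ± 0.06, Ugt8a by 1.32 ± 0.06 and Sox10 by 0.96 ± 0.06. Of 22 neuronal lineage genes, 0 rose and 19 fell (median -0.77, adjusted p 3.9e-08). The authors' deposited table gives -2.42 ± 0.12 for the synaptic vesicle gene Syt1, -1.75 ± 0.07 for Nsg2, -1.62 ± 0.10 for Dcx, a marker of young neurons, and -0.76 ± 0.04 for Map2. Of 15 astrocyte genes, 2 rose and 10 fell (median -0.43, adjusted p 0.031, and adjusted p 0.097 with a correlation of 0.05). They moved apart in the authors' deposited table, where Gja1 rose by 1.12 ± 0.04 and Aldoc, Slc4a4 and Fgfr3 had -1.05 ± 0.05, -0.93 ± 0.07 and -0.74 ± 0.06. Of 24 neural stem and progenitor cell genes, 6 rose and 14 fell (median -0.16, adjusted p 0.041). This call was lost with a correlation of 0.05 (adjusted p 0.15), with the voom statistic (0.053), with the filter on expression (0.070) and with ranks (0.069). The authors' deposited table gives -0.90 ± 0.05 for Fabp7, -1.02 ± 0.08 for Id3, -0.73 ± 0.06 for Dll1 and -0.09 ± 0.03 for Sox2 (adjusted p 0.014).

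Of 25 cholesterol biosynthesis genes, 0 rose and 22 fell at 8 h (median -0.32, adjusted p 3.7e-05), with -0.64 ± 0.05 for Acat2, -0.60 ± 0.05 for Tm7sf2, -0.50 ± 0.05 for Pmvk and -0.42 ± 0.04 for Dhcr7 in the authors' deposited table. Of 19 endoplasmic reticulum chaperones, 2 rose and 14 fell (median -0.20, adjusted p 0.024, and adjusted p 0.097 with a correlation of 0.05). The authors' deposited table gives -0.79 ± 0.07 for Sdf2l1, -0.51 ± 0.04 for Dnajc3 and -0.31 ± 0.04 for Manf, and a rise of 0.26 ± 0.03 for Canx. The other 13 lists did not pass. Of 36 immediate-early genes, 13 rose and 11 fell (median 0.10, adjusted p 0.21), and Fos had 0.10 ± 0.13 (adjusted p 0.54) in the authors' deposited table. Of 19 Notch pathway genes, 5 rose and 9 fell (adjusted p 0.22). The receptor gene Notch3 rose in the authors' deposited table by 1.29 ± 0.04, while Dll3 fell by 2.76 ± 0.11 and Mfng fell by 1.76 ± 0.14. Of 17 hypoxia-responsive genes, 6 rose and 2 fell (adjusted p 0.22), of 14 interferon response genes 4 rose and 3 fell (adjusted p 0.22), and of 14 NF-kB targets 5 rose and 3 fell (adjusted p 0.12). Of 20 glycolysis genes, 10 rose and 5 fell (adjusted p 0.24), of 22 heat shock genes 8 rose and 3 fell (adjusted p 0.22), and of 20 genes of base excision and strand break repair 6 rose and 9 fell (adjusted p 0.23). Of 14 mitochondrial biogenesis genes, 3 rose and 3 fell (adjusted p 0.88), and of 10 mitochondrially encoded genes 5 rose and 1 fell (adjusted p 0.42). Of 4 microglia genes 1 rose and 0 fell (adjusted p 0.70), of 8 endothelial and mural cell genes 1 rose and 2 fell (adjusted p 0.74), and of 7 ependymal genes 2 rose and 0 fell (adjusted p 0.22), with 0.78 ± 0.06 for Foxj1 in the authors' deposited table.

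**Figure D1:**
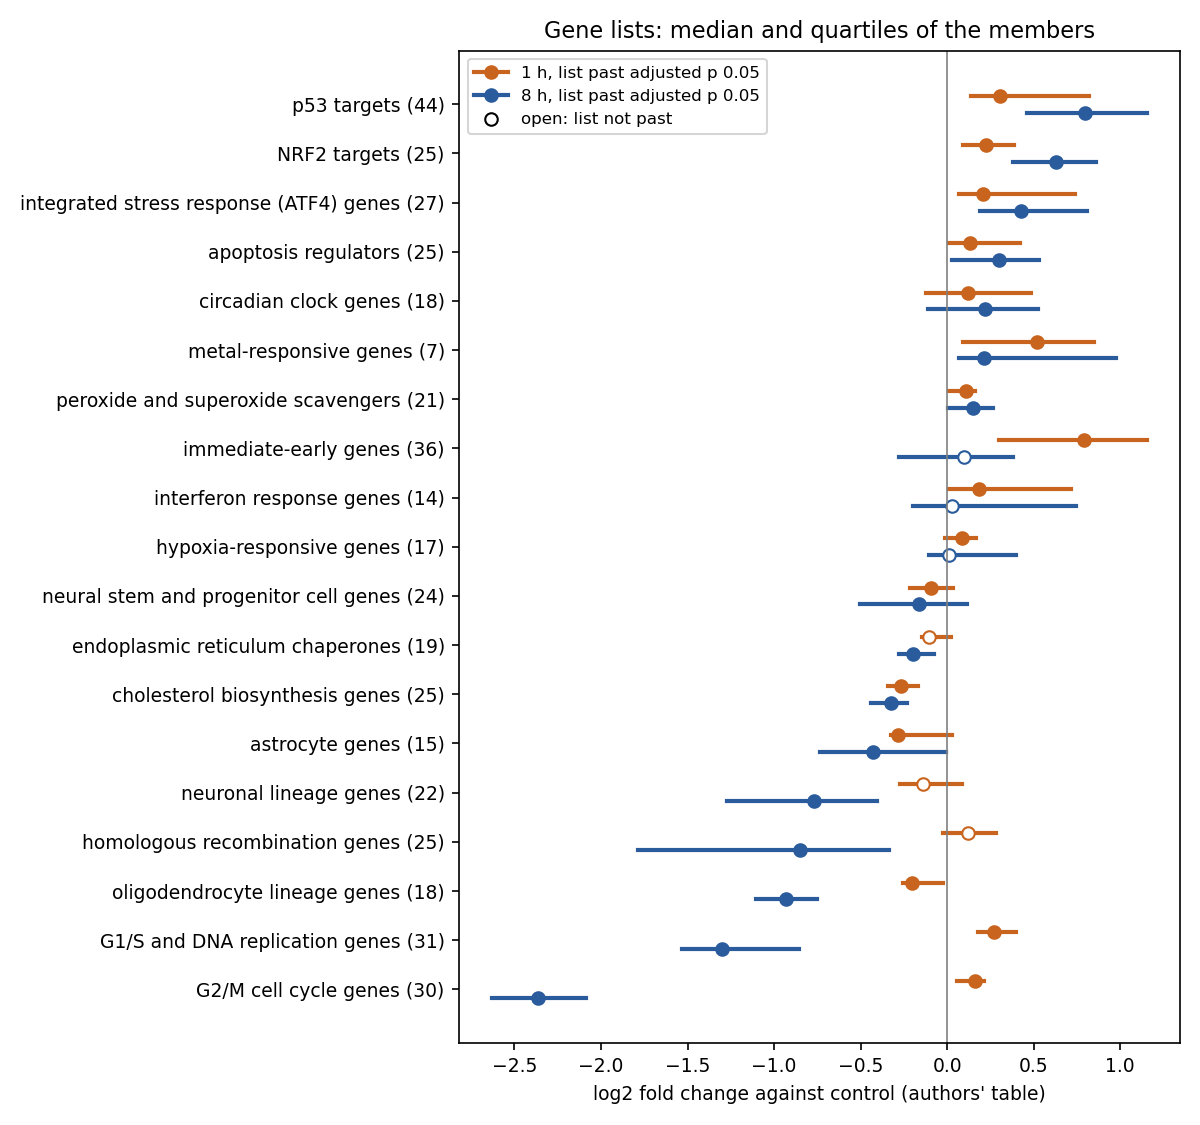
Median (point) and quartiles (bar) of the members' log2 fold changes against control at 1 h and 8 h, for each list that passed at either time, with the number of members in parentheses and open points where the list did not pass. The G2/M list lies at 0.16 at 1 h and at -2.37 at 8 h, and the p53 list at 0.30 and 0.80.

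**Figure D2:**
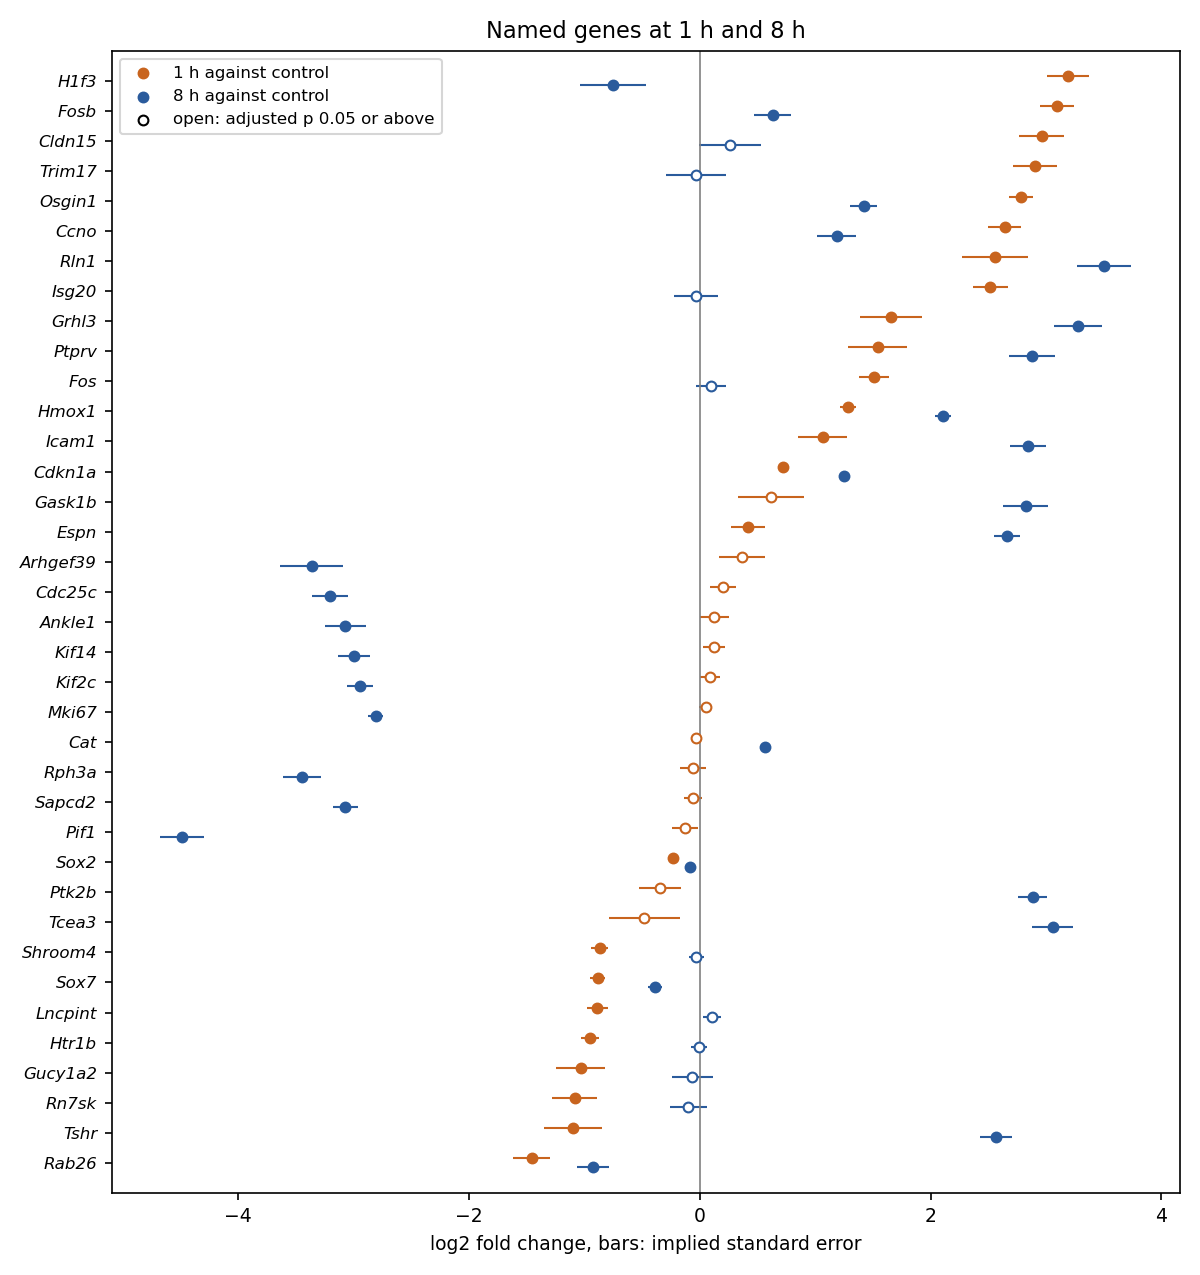
Log2 fold changes of named genes against control at 1 h and 8 h from the authors' deposited table, ordered by the 1 h value, with bars of 1 implied standard error and open points where the adjusted p was 0.05 or above. Pif1 lies at -0.13 at 1 h and at -4.49 at 8 h, and Rln1 at 2.55 and 3.50.

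The comparison of 8 h with 1 h tests directly where the exposure times differ. Cell cycle genes, homologous recombination genes, immediate-early genes and markers of the oligodendrocyte and neuronal lineages were lower at 8 h than at 1 h, and p53 and NRF2 targets were higher. The authors' deposited table calls 4687 genes higher and 5021 lower at 8 h than at 1 h, 62.7% of those tested, with a median absolute log2 fold change of 0.39 among them. Of the genes that differed at least 2-fold, 261 were higher and 1439 lower. Time in culture and exposure time cannot be told apart here, because no control sample is known to match each time.

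Of the genes that the naming rule admits, with a mean log2 CPM of at least 1, the furthest above its 1 h level in the authors' deposited table was Tshr, 3.67 ± 0.17 (adjusted p 3.6e-102), which had fallen at 1 h and rose by 2.56 against control at 8 h. The authors' deposited table further gives 3.54 ± 0.20 for Tcea3, 3.23 ± 0.13 for Ptk2b, 2.61 ± 0.25 for Fam47e, 2.47 ± 0.16 for Tgfbr3, 2.35 ± 0.07 for Pltp and 2.27 ± 0.11 for Perp, a p53 effector gene. Of the same genes, the furthest below its 1 h level in the authors' deposited table was Pif1, -4.36 ± 0.19, followed by H1f3, -3.94 ± 0.19 (adjusted p 1.9e-95). The authors' deposited table gives -3.73 ± 0.27 for Arhgef39, -3.40 ± 0.15 for Cdc25c, -3.39 ± 0.17 for Rph3a, -3.30 ± 0.18 for Mxd3, -3.23 ± 0.14 for Troap and -3.20 ± 0.18 for Ankle1. For Hmox1, Cdkn1a and Cat the authors' deposited table gives higher levels at 8 h, by 0.82 ± 0.07, 0.53 ± 0.03 and 0.60 ± 0.04, and for Sox2 by 0.14 ± 0.03 (adjusted p 3.8e-05). Fos was lower, -1.41 ± 0.13, and Mki67 was lower, -2.86 ± 0.06, in the authors' deposited table.

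All 30 G2/M genes and all 31 genes of the G1/S transition and DNA replication were lower at 8 h than at 1 h (medians -2.57 and -1.52, adjusted p 4.3e-97 and 2.3e-60). Among the latter, the authors' deposited table gives -1.96 ± 0.05 for Mcm5, -1.68 ± 0.04 for Rrm2, -1.62 ± 0.05 for the DNA methylation factor gene Uhrf1 and -1.42 ± 0.04 for Mcm6. Of 25 homologous recombination genes, 2 were higher and 20 lower (median -0.96, adjusted p 5.6e-10), with -2.54 ± 0.10 for Rad51ap1 and -2.24 ± 0.09 for Exo1 in the authors' deposited table. Of 36 immediate-early genes, 3 were higher and 28 lower (median -0.72, adjusted p 5.9e-09), with -2.46 ± 0.13 for Fosb, -2.24 ± 0.12 for Atf3, -2.15 ± 0.11 for Egr3 and -1.67 ± 0.07 for Nr4a1 in the authors' deposited table. Of 18 oligodendrocyte lineage genes, 1 was higher and 15 lower (median -0.81, adjusted p 7.4e-08), with -2.47 ± 0.06 for Pdgfra and -0.80 ± 0.06 for the myelin gene Mbp in the authors' deposited table. Of 22 neuronal lineage genes, 1 was higher and 16 lower (median -0.64, adjusted p 1.2e-05), with -0.95 ± 0.07 for Elavl3 and -1.33 ± 0.10 for Dcx in the authors' deposited table. Of 44 p53 targets, 31 were higher and 10 lower (median 0.35, adjusted p 7.9e-10), and of 25 NRF2 targets, 21 were higher and 2 lower (median 0.40, adjusted p 6.1e-07). The authors' deposited table gives 1.59 ± 0.05 for Dcxr, 1.08 ± 0.05 for Apaf1 and 0.76 ± 0.04 for the glutathione reductase gene Gsr, but -1.36 ± 0.08 for Osgin1 and -0.98 ± 0.06 for Bbc3. These 8 lists also passed with a correlation of 0.05.

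The other 21 lists had adjusted p from 0.12 to 0.91 for 8 h against 1 h. The lowest was that of 25 apoptosis regulators, 12 higher and 5 lower (adjusted p 0.12). Members went both ways in 27 integrated stress response genes (14 and 11, adjusted p 0.56), 24 stem and progenitor cell genes (8 and 12, adjusted p 0.79), 18 clock genes (9 and 7, adjusted p 0.79) and 19 Notch pathway genes (8 and 9, adjusted p 0.86). Counts were 4 and 12 of 19 endoplasmic reticulum chaperones (adjusted p 0.15), 5 and 12 of 25 cholesterol biosynthesis genes (0.63), 4 and 8 of 15 astrocyte genes (0.65) and 5 and 8 of 17 hypoxia-responsive genes (0.79). Counts were 6 and 5 of 21 scavengers (0.58), 5 and 1 of 7 metal-responsive genes (0.58), 5 and 9 of 20 base excision and strand break repair genes (0.56) and 6 and 4 of 14 NF-kB targets (0.64). Counts were 9 and 7 of 22 heat shock genes (0.65), 7 and 6 of 20 glycolysis genes (0.79), 2 and 5 of 14 interferon response genes (0.91), 3 and 3 of 14 mitochondrial biogenesis genes (0.91) and 4 and 0 of 10 mitochondrially encoded genes (0.64). Among rare cell types, counts were 1 and 3 of 4 microglia genes (0.79), 1 and 3 of 8 endothelial and mural cell genes (0.75) and 2 and 1 of 7 ependymal genes (0.75).

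Over the 29 lists, 16 passed at 1 h (12 higher, 4 lower), 16 at 8 h (7 higher, 9 lower) and 8 for 8 h against 1 h (2 higher, 6 lower). With a correlation of 0.05 in place of an estimated correlation, 9, 11 and 8 lists passed. Adjusted over the list alone, the counts of members that rose or fell were the same as over all genes in 20 lists at 1 h, 23 at 8 h and 25 for 8 h against 1 h, and differed by at most 2 genes in the rest. The median, the mean and the test differed in sign for 10 list results, and all of these had adjusted p of 0.12 or above. They were the Notch pathway, endoplasmic reticulum chaperone and mitochondrially encoded lists at 1 h and the microglia list at 8 h. In the comparison of 8 h with 1 h they were the circadian clock, ependymal, glycolysis, interferon response, mitochondrial biogenesis and mitochondrially encoded lists.

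The overlap of both exposure times asks how far the same genes changed. By the calls of the authors' deposited table, 1208 genes rose at both times, where 868 would by chance if the calls were independent, and 1414 fell at both, where 971 would. A further 619 genes rose at 1 h and fell at 8 h, where 894 would, and 881 fell at 1 h and rose at 8 h, where 943 would. Changes at 1 h alone were called for 2484 genes, at 8 h alone for 4492, and at neither time for 4380. Both comparisons use the same control samples, which by itself favours equal signs. In simulated unchanged groups with shared controls the log2 fold changes of both times correlated at 0.545 across genes, against 0.186 observed. The simulated values are noise alone, drawn from the implied standard errors without modelling the shared animals, so they are no baseline for changed genes. On average 0.01 simulated genes were called in the same direction, beside 2622 observed. Few calls can arise where no gene changes, so this does not tell how many of the 2622 owe to shared controls. The covariance was 0.0479 observed and 0.0147 simulated, and 57.2% of genes had the same sign, against 67.2% simulated. Genes are not independent replicates, and the controls could not be split, so part of the excess in equal directions may be due to the shared controls.

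**Figure D3:**
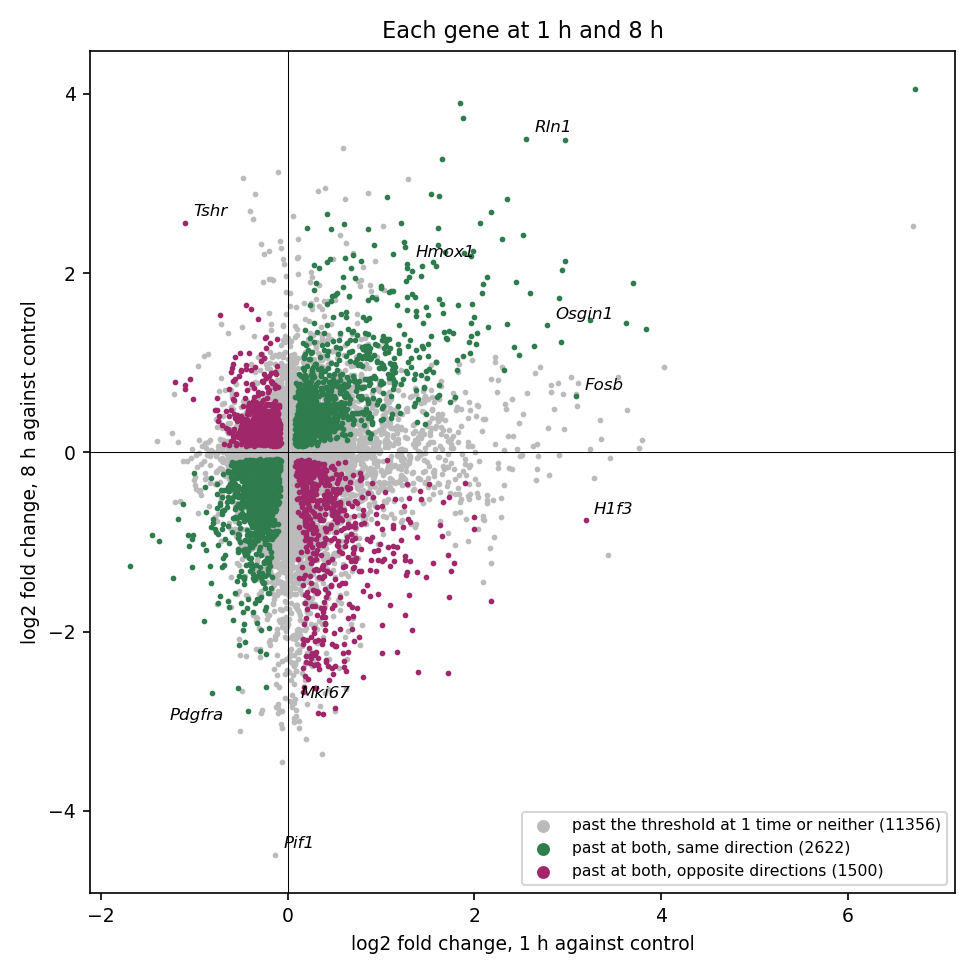
Log2 fold change against control of each of 15478 genes at 1 h (horizontal axis) and 8 h (vertical axis), from the authors' deposited table, with colours for genes past the threshold at both times. Same directions hold for 2622 genes and opposite directions for 1500, H1f3 and Tshr among them.

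The authors tested the same comparisons with both of their tables. At adjusted p below 0.05 the GLM and the voom version of the authors' deposited table both called 6293 genes at 1 h, 8113 at 8 h and 9200 for 8 h against 1 h, with 0 genes in opposite directions. GLM alone called 313, 501 and 508 genes, and voom alone 125, 53 and 53. The log2 fold changes of both correlated at 0.997, 0.997 and 0.999 across genes, which are not independent replicates.

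The authors' deposited table of hallmark sets, tested with camera, had its smallest adjusted p among higher sets at 1 h for TNFA signaling via NFKB (9.8e-21), the p53 pathway (8.7e-16), apoptosis (1.5e-05), UV response up (5.0e-05) and E2F targets (1.4e-04). Its smallest among lower sets were those of the mitotic spindle (8.0e-07), UV response down (2.6e-05), protein secretion (0.0026), Notch signaling (0.0047) and angiogenesis (0.030). At 8 h the authors' deposited table has, among higher sets, the p53 pathway (2.6e-18), the reactive oxygen species pathway (2.2e-05), xenobiotic metabolism (3.9e-04), TNFA signaling via NFKB (0.0077) and hypoxia (0.0077). Lower in the authors' deposited table at 8 h were E2F targets (3.4e-34), the G2M checkpoint (1.8e-31), the mitotic spindle (1.4e-05) and spermatogenesis (3.1e-05), while cholesterol homeostasis did not pass with camera (0.071). With the authors' overlap test that set passed as lower at 8 h, with 40 of 70 genes called (adjusted p 1.8e-05). For 8 h against 1 h the authors' deposited table has, among higher sets, protein secretion (3.8e-04), the p53 pathway (0.0054), angiogenesis (0.0054), UV response down (0.0063) and Notch signaling (0.035). Lower at 8 h than at 1 h in the authors' deposited table were E2F targets (4.7e-43), the G2M checkpoint (6.2e-29), spermatogenesis (3.8e-04), MYC targets V1 (0.031) and TNFA signaling via NFKB (0.031). Of the 50 hallmark sets, the camera version of the authors' deposited table passes 14 higher and 5 lower at 1 h, 9 and 4 at 8 h, and 5 and 5 for 8 h against 1 h. The overlap version of the authors' deposited table passes 13 and 7, 14 and 5, and 8 and 5.

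In the authors' deposited table of KEGG sets the ribosome (3.6e-09), p53 signaling, coronavirus disease, ferroptosis and systemic lupus erythematosus led the higher sets at 1 h, and Hedgehog signaling (6.1e-07), phosphatidylinositol signaling, adherens junction, focal adhesion and regulation of the actin cytoskeleton the lower ones. At 8 h the authors' deposited table has the proteasome (4.6e-05), ferroptosis, p53 signaling, apoptosis and mitophagy as higher, and DNA replication (1.1e-15), cell cycle, oocyte maturation, homologous recombination and the GABAergic synapse as lower. For 8 h against 1 h the authors' deposited table has proteoglycans in cancer (0.0046), adherens junction, autophagy, Hedgehog signaling and alcoholic liver disease as higher, and DNA replication (3.5e-17), cell cycle, homologous recombination, base excision repair and the Fanconi anemia pathway as lower. The authors' deposited table of WikiPathways sets gives, as higher at 1 h, cytoplasmic ribosomal proteins (3.0e-10), p53 signaling, oxidative stress response, Nfe2l2 activation by phytochemicals and the oxidative stress and redox pathway. As lower at 1 h the authors' deposited table gives cholesterol biosynthesis (1.5e-04), focal adhesion, focal segmental glomerulosclerosis, regulation of the actin cytoskeleton and cholesterol metabolism. At 8 h the authors' deposited table has oxidative stress response (4.9e-06), Nfe2l2 activation, the redox pathway, p53 signaling and alpha 6 beta 4 integrin signaling as higher. As lower it has a set of 2 genes around PDGFR-alpha (6.4e-15), G1 to S control, a set of 3 genes named osteoblast signaling, NOVA-regulated synaptic proteins and cholesterol metabolism. For 8 h against 1 h the authors' deposited table has alpha 6 beta 4 integrin signaling (9.3e-05), focal segmental glomerulosclerosis, IL-6 signaling, ErbB signaling and integrin-mediated adhesion as higher. As lower it has the same sets around PDGFR-alpha (5.9e-13), G1 to S control and osteoblast signaling, followed by mismatch repair and dopaminergic neurogenesis.

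In the authors' deposited table of Reactome sets the smallest adjusted p at 1 h was that of the activation of NOXA, a set of 1 gene (1.4e-19), followed by 4 sets of ribosomal translation, namely free small subunits (2.9e-11), SRP-dependent targeting, L13a-mediated silencing and nonsense-mediated decay. Lower at 1 h in the authors' deposited table were the RAC1, RHOU and RHOV GTPase cycles (2.8e-05 for RAC1) and cohesin loading. At 8 h the authors' deposited table has the activation of NOXA (1.8e-06), the response to chemical stress, RUNX3 regulation, ornithine decarboxylase regulation and stabilization of p53 as higher. As lower it has the pre-replicative complex (1.8e-16), phosphorylation of Emi1, a set of 6 genes, ATR activation and a pair of kinetochore signal sets. For 8 h against 1 h the authors' deposited table has the RHOV (5.8e-07) and RHOU cycles, cargo targeting to the cilium, non-integrin membrane interactions and hemidesmosome assembly as higher. As lower it has the pre-replicative complex (3.6e-20), ATR activation, phosphorylation of Emi1, cyclin events of the G2/M transition and a kinetochore signal set. In the authors' deposited table of Gene Ontology overlap tests, the 5 highest-ranked sets that rose at 1 h were all ribosomal, with 75 of 95 genes of the cytosolic ribosome called (1.7e-30), and those that fell were broad developmental sets led by multicellular organism development (6.2e-55). At 8 h the authors' deposited table has cytoplasm (2.9e-40), cytosol, intracellular structure, organonitrogen metabolism and cellular entity as higher, and trans-synaptic signaling (3.3e-33), 3 related synaptic sets and regulation of biological process as lower. For 8 h against 1 h the authors' deposited table has cytoplasm (7.0e-48) and 4 broad cellular sets as higher, and anterograde trans-synaptic signaling (6.4e-12) with 4 related synaptic sets as lower. At adjusted p below 0.05, higher and lower sets at 1 h numbered 9 and 24 of 349 in KEGG, 12 and 28 of 198 in WikiPathways, 73 and 91 of 1664 in Reactome and 49 and 600 of 21197 in Gene Ontology in the authors' deposited table. At 8 h the authors' deposited table has 18 and 15, 16 and 7, 135 and 112, and 136 and 326, and for 8 h against 1 h it has 17 and 7, 11 and 6, 88 and 98, and 346 and 109.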

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

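The tests of fewer oligodendrocyte-lineage cells and of a shift by the authors' normalization were chosen after the result was seen, and the test of gene length before. Each value in this paragraph is here because the effect against control differs between the exposure times by the test of 8 h against 1 h. Past the threshold in opposite directions against control, and also different between the times, were 1500 genes. The lists that differ between the times are, with their adjusted p, G2/M genes (4.3e-97), G1/S and DNA replication genes (2.3e-60), p53 targets (7.9e-10), homologous recombination genes (5.6e-10), immediate-early genes (5.9e-09), oligodendrocyte lineage genes (7.4e-08), NRF2 targets (6.1e-07) and neuronal lineage genes (1.2e-05). Among genes named for the size of their change against control or always given, those with opposite calls at both times are H1f3, with a log2 fold change of -3.94 for 8 h against 1 h in the authors' deposited table, and Tshr, with 3.67.

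Lists of 2 lineages fell at 8 h and differ between the times, the oligodendrocyte lineage (17 of 18 genes, median -0.93), weighed here, and the neuronal lineage (19 of 22 genes, median -0.77), for which no explanation was tested. Gene length does not account for the fall of the oligodendrocyte list. Its median was -0.98 after the trends with genomic span, exon length, GC content and mean level were removed together. A shift of all genes alike by the authors' normalization would move the list and the other genes together. The list lay below the others, with a difference of medians of -0.94 (quartiles of the members -1.11 to -0.76). That argues against such a shift as the cause of the list's place relative to them. The absolute change of the list stays open, because the deposited fold changes are centred (median of the other genes 0.0057). Fewer oligodendrocyte-lineage cells cannot be told apart from lower transcription within them: the members' log2 fold changes had an SD of 0.613, beside a typical implied standard error of 0.0916, but of 0.387 without Pdgfra, and markers that other cells share would fall less. Time in culture, which the groups cannot separate from peroxide, stays open as well.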

How the results depend on the processing

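All the alternatives reported here were planned. No list or named gene result that passed changed direction under any of them, and the neighbour, span and family results were not run under them. Among list results that did not pass, direction changed with voom for Notch pathway genes at 8 h against 1 h (adjusted p 0.933), with the filter on expression for endothelial genes at 1 h (0.761) and microglia genes at 8 h against 1 h (0.628), and with ranks for repair genes at 1 h (0.998) and clock genes at 8 h against 1 h (0.848); the cause was not tested. With a minimum of 1 for the absolute log2 fold change, 646 genes changed at 1 h (618 higher, 28 lower), 1307 at 8 h (408 and 899) and 1700 for 8 h against 1 h (261 and 1439), fewer because the threshold is stricter. The share that was higher then moved to 95.7%, 31.2% and 15.4%, and by construction 226 of the 391 named gene results no longer passed. At adjusted p below 0.01, 784 genes rose at both times and 355 rose at 1 h and fell at 8 h, fewer for the same reason, and 5 named gene results no longer passed. With an inter-gene correlation of 0.05, 9 lists passed at 1 h in place of 16, because a larger assumed correlation widens each test. Of 87 list results, 40 passed, and of these 12 were lost with that correlation, 5 with ranks, 4 with the filter on expression and 1 with voom; for the last 3 the cause was not tested. Counts of changed genes at 1 h, 8 h and 8 h against 1 h stayed within 1.5 times the reported ones with voom (6418, 8166 and 9253), median centring (6593, 8594 and 9744), genes with a mean log2 CPM of at least 1 (5855, 7735 and 8355), adjusted p below 0.01 (5048, 7177 and 8345) and correction over the 3 comparisons together (6839, 8573 and 9564). Fewer genes were higher than lower in each comparison as reported, and this turned for 8 h against 1 h with centring (4934 higher, 4810 lower) and with the filter on expression (4452 and 3903), and at 8 h with that filter (3878 and 3857). Voom added 2 named gene results and centring 1, and the filter on expression kept all 357 that it still tested.

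No paired analysis was possible because the deposited tables used here hold no values of single samples. For the same reason these alternatives were not run: DESeq2, other size factors, no filter on genes, no block for the animal, leaving out each replicate, fits of 2 groups alone, other splits of the samples, separate controls for each time, and an estimated correlation or a rotation test for lists. Depth per sample is unknown, so what it limits among faint genes could not be measured.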

Other observations

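The tests of scatter, of genomic DNA near expressed genes, of transcription by distance and of new transcript from long genes were chosen after the result was seen, as were the level and distance limits they use and the gene families below. Many genes with very little RNA gained some at 1 h. Among 4108 genes with a mean below 2 log2 CPM, 563 rose at least 2-fold at 1 h and 23 fell, while 252 rose and 440 fell as much at 8 h. The genes that rose lie behind expressed genes more often than others do. Of 560 with coordinates, 25.0% start within 5 kb past the end of an expressed gene on the same strand, against 6.98% of 3540 other low genes (Fisher's exact p 1.0e-32). Within 50 kb it was 62.5% against 26.5%. For an expressed gene of the opposite strand ending towards them the shares were 7.14% against 6.38% within 5 kb (exact p 0.52) and 28.6% against 24.5% within 50 kb (exact p 0.046). For an expressed gene downstream on the same strand they were 6.61% against 4.21% (exact p 0.016) and 31.8% against 22.7% (exact p 5.5e-06), so within 50 kb neighbours of both these kinds were also more frequent, by less. Low genes named in the report with this arrangement include Cldn15, Psmb8, Esam and Ak7, with log2 fold changes of 2.96, 1.78, 1.77 and 1.46 at 1 h and of 0.26, -0.18, 0.04 and 0.56 at 8 h in the authors' deposited table.

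Gene span also went with the change at 1 h. Among the 8675 protein-coding genes used for this, the shortest eighth (median span 4.24 kb) had a median log2 fold change of 0.08 at 1 h and the longest (178 kb) one of -0.29, and the shares that fell were 6.91% and 81.9%. At 8 h these medians were 0.05 and -0.07. Gene families were also tested, without a test of their span. Because the libraries were poly-A, the values of histone genes need not hold for their RNA without a poly-A tail. Of 79 ribosomal protein genes, with a median span of 3.24 kb, 71 rose and 0 fell (median 0.19, adjusted p over 8 families 4.0e-15), and of 28 histone genes (1.76 kb) 23 rose and 0 fell (median 0.50, adjusted p 1.4e-16). Of 29 collagen genes (114 kb), 2 rose and 11 fell (adjusted p 0.016), and of 36 kinesin genes (50.5 kb) 3 rose and 16 fell (adjusted p 0.0088). Of 37 proteasome genes (12.4 kb) 18 rose and 1 fell (adjusted p 0.0015), while 333 numbered zinc finger genes (16.5 kb, 67 and 75, adjusted p 0.77) and 8 chaperonin genes (13.04 kb, 2 and 0, adjusted p 0.19) did not pass. At 8 h, 33 proteasome genes rose and 0 fell (median 0.21, adjusted p 1.3e-06), 48 ribosomal protein genes rose and 2 fell (adjusted p 0.012), 4 histone genes rose and 16 fell (median -0.46, adjusted p 0.036) and 8 kinesin genes rose and 23 fell (adjusted p 1.2e-09). The collagen, zinc finger and chaperonin families did not pass at 8 h (adjusted p 0.57, 0.64 and 0.64). Between 1 h and 8 h the adjusted p was 4.2e-12 for histone, 7.5e-05 for kinesin and 0.014 for proteasome genes, and from 0.10 to 0.79 for the ribosomal protein, collagen, zinc finger and chaperonin families.

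On the rise of low genes at 1 h, scatter is argued against by the median of all 4108 low genes, not chosen by their change. Their mean level does include the 1 h samples. The median was 0.25 at 1 h and -0.02 at 8 h. Over all genes the 1 h median went down with level, from 0.37 for a mean below 0 log2 CPM to -0.06 for a mean of at least 6. The cause of this trend with level was not tested. Of 586 low genes that changed at least 2-fold, 96.1% rose, against 36.4% at 8 h, but this restates the counts that prompted the question. Genomic DNA in the 1 h libraries is argued against as the whole cause for genes just behind a same-strand gene. Their median, adjusted for mean level, lay 0.32 above that of genes behind an opposite-strand end (95% interval 0.22 to 0.44, 337 and 216 genes). This interval and those below come from 1000 bootstraps of chromosomes. They hold no spread between animals or libraries, which could not be resampled. A share of DNA reads on both strands cannot be excluded, since the difference shows only what the strands do not share. Low genes within 5 kb of an opposite-strand end had a median of 0.39 at 1 h, against 0.23 for the others. For the genes over 50 kb from any expressed gene, genomic DNA cannot be told apart. There the partial rank correlation of the 1 h change with exon length, given mean level, was -0.067 (-0.131 to -0.005, 1059 genes). This met the bound set beforehand for excluding genomic DNA. But the same correlation was -0.220 at 8 h, so 0 was a wrong baseline, and this label was changed after the value was seen. Transcription running past the ends of upstream genes could add such reads. Within 50 kb the change fell with the distance to the upstream gene. The partial rank correlation given mean level was -0.237 (-0.287 to -0.185, 1288 genes), and -0.000302 for opposite strands. Within 5 kb it was 0.044 with distance (387 genes), where the prediction written beforehand was a fall. The rise with the upstream gene's level that was predicted beforehand was not seen there either (0.053, -0.043 to 0.140). That value met the bound set beforehand for excluding such transcription. Such transcription is left open because the interval reaches the bound of 0.1, a reading also chosen afterwards. Of the 560 genes 66 lie over 50 kb from any expressed gene, and how far such transcription runs was not measured.

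On the fall of long genes at 1 h, the slope of log2 fold change per 10-fold span was -0.213 (95% interval -0.226 to -0.203). The intervals of slopes also come from bootstraps of chromosomes and hold no spread between animals or libraries. Exon length is argued against as the whole cause, since with it in the fit the slope was -0.164 (-0.176 to -0.151), or 0.769 of the former, and GC content likewise, with a slope of -0.220. Less new transcript from long genes within the first hour could give such a slope and would let it shrink later: with exon length, GC content and mean level in the fit it was -0.172 at 1 h and -0.066 at 8 h, and 0.107 for 8 h against 1 h (0.083 to 0.131). Degradation of RNA and differences between libraries were not tested, and new transcripts were not measured, so these stay open.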
